A study of Mus musculus with 3 samples.

How the data were processed

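RNA was measured in 3 libraries, 1 per cell population, from mice that the labels give as C57/bl6: Sox9+ digit cells at embryonic day 13.5 (E13.5), and Lgr5+ interzone and Lgr5− non-interzone forelimb digit cells at embryonic day 14.5 (E14.5). Per the labels' protocols, digits were digested with TrypLE and DNase, GFP-positive and GFP-negative cells were separated on a flow cytometer, and cDNA libraries were made from 10 ng of total RNA with a SMARTer ultra-low-input kit and read on an Illumina HiSeq. Kits of this type prime on poly(A) tails and do not mark the strand. Low input and amplification by this kit raise the noise of weakly expressed genes, and the number of amplification cycles, the number of cells and the read length are not given in the sources used here. HISAT2 and the mouse build mm10 (GRCm38) are named in the submitters' processing notes. The tool that made the expression values, the gene annotation, and the handling of reads that map to several places are not given in the sources used here.

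The deposited files hold 1 value per gene symbol in FPKM (fragments scaled by transcript length and by the mapped fragments of the library), as made by the authors and rounded to 2 decimals. FPKM divides by gene length and by the library's total, so the values are shares of a library and not numbers of molecules, and a few very abundant RNAs can shift all others. Each file listed the same 23284 symbols, of which 25 had been turned into dates by a spreadsheet and were not used by name. No mitochondrially encoded gene symbol was listed, so that sign of RNA quality could not be read. Genes at exactly 0 numbered 6520 in the Sox9+ library, 6751 in the Lgr5+ library and 6461 in the Lgr5− library, and such a gene is said here only to be listed at 0. The files give no read counts, so the depth of each library is unknown and no counting interval could be given. A search for the step that 1 fragment would leave in low values, over 4559 single-transcript genes, gave scores of 0.206 in the Sox9+ library, 0.209 in the Lgr5+ library and 0.22 in the Lgr5− library. With gene lengths shuffled the best scores were 0.24, 0.241 and 0.173, and simulated fragments gave 0.922 to 0.944 and the right depth in 6 of 6 runs, so the steps gave no usable depth. A search over intronless genes was tried as well and had too few genes to use. Among 26 short RNA genes above 1 FPKM in both libraries, 5 shared a ratio of Sox9+ to Lgr5− values of 1.116 (within 0.5%), which would make the Lgr5− library 1.116 times as deep if these genes hold equal counts. That ratio was picked as the most repeated of all and no chance level was computed for it, so it is not used as a depth. No such ratio was shared by more than 3 genes with the Lgr5+ library, so the relative depth of that library was not derived.

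Differences were computed as log2 ratios of FPKM + 1 in the 3 pairs of libraries, and a fold is the ratio of FPKM + 1. A gene counted as measured with at least 1 FPKM in the higher library, and as different at 2-fold or more. With 1 library per group no test was run and no p-value is given. For each gene list with at least 3 measured members, the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins (seed 1), and a list is said to stand apart when its percentile was under 2.5 or over 97.5. These percentiles describe these libraries and are not tests. Across genes, Pearson's r of log2 values was 0.957 between the Lgr5+ and Lgr5− libraries and 0.942 between each of them and the Sox9+ library, and genes are not independent replicates. In data simulated for the Lgr5+ and Lgr5− libraries with Poisson sampling at an assumed depth, 91.4% of 70 genes changed 3-fold, 100.0% of 70 changed 6-fold and 1.7% of 60 changed 1.5-fold were called in the right direction, none of 11832 unchanged genes was called, and 5.0% of 60 unshifted lists stood apart. That simulation holds no amplification or biological noise. Its unshifted lists were drawn at random from unchanged genes, so a share near 5.0% was set by construction. It does not show how often a list of related genes would stand apart by chance.

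Groups, comparisons, thresholds, gene lists, the rule for named genes and the alternative settings were chosen before the data were examined. The lists covered the interzone, articular and synovial tissue, cartilage, hypertrophic and pre-hypertrophic chondrocytes (the maturation genes), perichondrium and bone, tendon, limb patterning, hindlimb, forelimb, muscle, epidermis, endothelium, red blood cells, macrophages, Schwann cells and melanocytes, the cell cycle, the Wnt, BMP and TGF-beta, hedgehog and Notch pathways, retinoic acid, hypoxia and glycolysis, dissociation stress, Y-linked, ribosomal protein and histone genes. Older symbols in the files were matched through a reference table, such as Lect1, Emr1, Pkm2 and Cyr61, and Hbb-bt, Ahsp and Ca9 had no match. The rule named, in each pair and among genes of at least 10 FPKM in the higher library, the 10 with the highest and the 10 with the lowest log2 ratio, leaving out predicted genes without a proper name, small RNA and X-inactivation genes. It also named Lgr5 and Sox9, Col22a1 and Gdf5 (chosen from prior knowledge of work on Lgr5+ joint cells and not from the labels), and 2 to 4 members of each list with the largest difference, of which a few are not reported here. Col2a1, Rn45s, the level of C1qb in the first comparison, Runx2 and Runx3 in the last, the examples of genes that set a single library apart, and Ihh, Msx1 and the other genes drawn in the plot of selected genes outside the rule were chosen after their values were seen. Col10a1, Panx3 and Spp1 in the first comparison and Prg4 and Tnc in the second were also chosen after their values were seen. Further lists of heat shock, endoplasmic reticulum stress, proximal limb, muscle, epidermal and mast cell genes were added after the data were seen.

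The alternatives were pseudocounts of 0.1 and 5, no minimum, a minimum of 10 FPKM, a 4-fold threshold, scaling to the same total in each library (TPM), by median of ratios, by upper quartile, by quantile normalization or by the sum without the most abundant and haemoglobin genes, the mean over list members, and unmatched random lists. Gene spans came from GENCODE release M21 on GRCm38. Reads of near-identical copies, such as the globin genes, Hspa1a and Hspa1b, and of pseudogenes, overlapping and antisense genes may have been split in ways the files do not show. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.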

Results

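The data were RNA-seq profiles of cells sorted from the digits of mouse embryos while the finger joints form. There were 3 libraries, 1 for each of 3 cell populations. Sox9+ cells came from digits at E13.5 of mice carrying a Sox9-eGFP reporter, and Sox9 is the master transcription factor of chondrocytes. Lgr5+ cells, which the labels call interzone cells, came from forelimb digits at E14.5 of Lgr5-eGFP-CreERT2 mice. The interzone is the band of cells that marks the site of a future joint. Lgr5− cells were the GFP-negative digit cells of the same line and day, which the labels call non-interzone. The sort was by GFP and not by position, so interzone cells without reporter signal may be among them. Each library listed the same 23284 genes in FPKM, and the FPKM summed to 593871 in the Sox9+ library, 534025 in the Lgr5+ library and 547115 in the Lgr5− library. The libraries were similarly complete, with 11924 genes at 1 FPKM or more in the Sox9+ library, 12002 in the Lgr5+ library and 11969 in the Lgr5− library. The ribosomal RNA precursor Rn45s took 6.43% of the summed FPKM in the Sox9+ library and 6.13% in the Lgr5− library but 1.86% in the Lgr5+ library. Haemoglobin genes took 1.01% of the sum in the Lgr5− library, against 0.029% in the Sox9+ library and 0.036% in the Lgr5+ library. Folds are ratios of FPKM + 1, which understates the differences of low genes. No group had a replicate, so no difference given here has a replicate check, no p-value or error could be computed, and each comparison is between libraries and not between conditions.

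The sorting genes and the joint genes Gdf5 and Col22a1 were read first. Lgr5, a receptor for R-spondins (GRCm38 chromosome 10, 115450311 to 115587780, minus strand), stood at 26.8 FPKM in the Lgr5+ library, 1.36 FPKM in the Lgr5− library and 3.48 FPKM in the Sox9+ library. Sox9 (chromosome 11, 112782224 to 112787760, plus strand) stood at 332 FPKM in the Lgr5+ library, 254.7 FPKM in the Sox9+ library and 147.1 FPKM in the Lgr5− library. Sox9 RNA was therefore not highest in the library sorted by its reporter, and it was 2.25-fold higher in the Lgr5+ library than in the Lgr5− library. Gdf5, the growth factor that marks the interzone (chromosome 2, 155941023 to 155945367, minus strand), reached 614.8 FPKM in the Lgr5+ library, against 71.7 FPKM in the Lgr5− library and 59.9 FPKM in the Sox9+ library. Col22a1, a collagen of tissue junctions and articular cartilage (chromosome 15, 71795795 to 72034227, minus strand), stood at 15.8, 1.93 and 1.5 FPKM in the same order. All 4 are annotated as protein-coding genes, and the spans given are those of the whole gene. The Gdf5 fold of the Lgr5+ library was 8.47 over the Lgr5− library and 10.1 over the Sox9+ library, and the Col22a1 fold was 5.74 and 6.73.

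**Figure D1:**
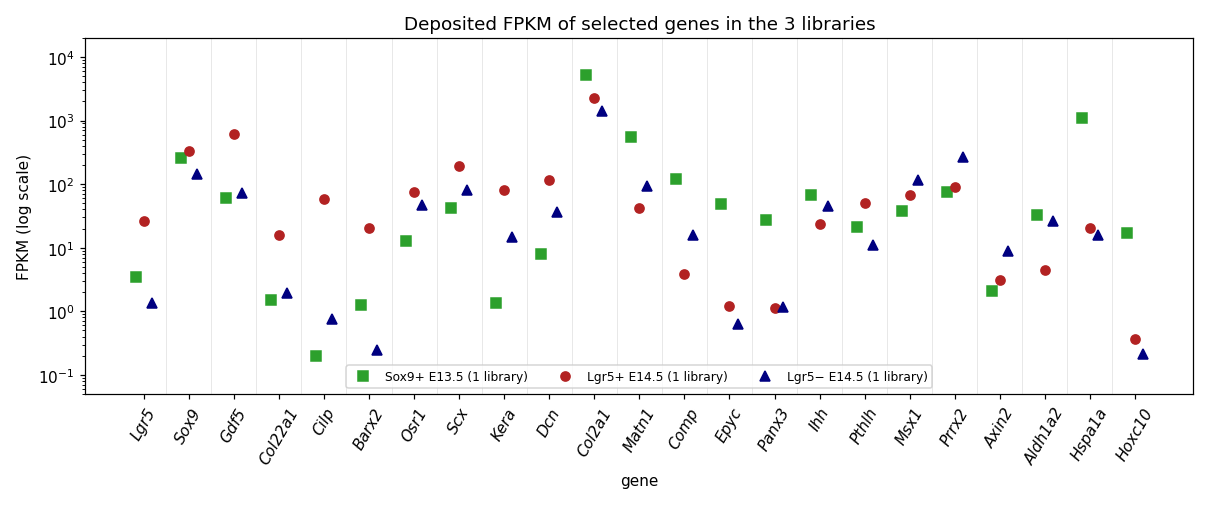
Deposited FPKM (log axis) of 23 genes in the 3 libraries, 1 library per population, with 1 point per gene and library and no error because there are no replicates. Gdf5 stands at 614.8 FPKM in the Lgr5+ library against 71.7 and 59.9 FPKM in the others, and Hspa1a at 1116 FPKM in the Sox9+ library against 20.2 and 16.1 FPKM.

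The comparison of Lgr5+ with Lgr5− cells asked what set Lgr5+ cells apart from GFP-negative digit cells of the same day and mouse line. By list medians, interzone, tendon and cartilage genes were higher in the Lgr5+ library. Genes of chondrocyte maturation, perichondrium and bone, limb patterning and retinoic acid handling were lower. In most of these lists, most members lay within 2-fold. Muscle and epidermal genes were also higher and red blood cell genes lower, each by a median larger in size than that of the interzone list. Of 12438 genes measured, 453 were at least 2-fold higher in the Lgr5+ library and 235 at least 2-fold lower. The excess of higher genes kept its direction but not its size under other scalings, with 616 and 355 after rescaling to TPM, 415 and 268 with the sum without the most abundant genes, 398 and 275 with quantile normalization, 387 and 285 with median of ratios and 375 and 294 with upper quartile. The highest fold among genes higher in the Lgr5+ library was that of Cilp, which encodes an articular cartilage matrix protein and stood at 58 FPKM against 0.75 FPKM, 33.7-fold higher. The homeobox gene Barx2 was 17.1-fold higher, the secreted chondrogenic factor Scrg1 13.7-fold, the EGF receptor ligand Btc 13-fold, the zinc finger gene Glis1 11.8-fold and the BMP and Nodal antagonist Cer1 11.7-fold. Msc, Adck3 and C2cd4b completed the 10 highest with Lgr5 itself, at 10.4-fold, 10.1-fold and 10-fold.

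Of the 19 measured interzone genes, 10 were at least 2-fold higher in the Lgr5+ library and none 2-fold lower, and their median log2 ratio of 1.01 lay above all 10000 matched random lists. Gdf5, Dkk3 (4.28-fold), Barx1 (3.75-fold) and Osr2 (3.2-fold) led this list. The list of articular and synovial genes did not stand apart as a whole, with a median of 0.24 at percentile 95.06, although 3 of its 14 measured members were at least 2-fold higher: Cilp, Col22a1 and Thbs4 (3.53-fold). Tendon and ligament genes were higher, with 7 of 16 members at least 2-fold higher, none 2-fold lower and a median of 0.74, above all random lists. Among them were Fmod (5.33-fold), Kera (5.26-fold), Six2 (5.07-fold) and Dcn (3.14-fold), of which Fmod, Kera and Dcn encode small leucine-rich proteoglycans.

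Cartilage genes had a median of 0.69, above all random lists, with 6 of 23 members at least 2-fold higher. Sox6 (3.31-fold) and Sox5 (3.27-fold), which act with Sox9 in chondrogenesis, and the matrix gene Chad (2.93-fold) were higher. Comp, a matrix protein of maturing cartilage, was 3.42-fold lower, at 3.9 against 15.8 FPKM, and was 1 of 2 members at least 2-fold lower. Genes of hypertrophic and pre-hypertrophic chondrocytes had a median of −0.55, below all random lists, with 4 of 12 members at least 2-fold lower. Their leading members were Runx3 (4.22-fold lower), Runx2 (3.78-fold lower) and Sp7 (3.51-fold lower), transcription factors of chondrocyte maturation and bone formation. Pthlh, the secreted inhibitor of that maturation, was the 1 member at least 2-fold higher, at 50.1 against 11 FPKM. The other 7 of the 12 lay within 2-fold. Among these, Col10a1 (2.24 against 2.17 FPKM), Panx3 (1.14 against 1.16 FPKM) and Spp1 (2.13 against 2.5 FPKM) were low in both libraries and hardly differed. Perichondrium and bone genes had a median of −0.32 at percentile 0.02, although 12 of 18 members lay within 2-fold. Dlx5 (3.36-fold) and Twist1 (3.14-fold) were among 4 at least 2-fold lower. Foxc1 (2.64-fold) and Fgfr2 (2.53-fold) were the 2 at least 2-fold higher. Limb patterning genes had a median of −0.45, below all random lists, with 6 of 22 members at least 2-fold lower and none 2-fold higher. Prrx2 (2.86-fold), Tbx3 (2.86-fold), Tfap2a (2.71-fold) and Tbx2 (2.51-fold), all transcription factor genes, had the largest differences.

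Signalling genes differed by pathway. Retinoic acid genes had a median of −0.85, below all random lists, and 7 of 14 members were at least 2-fold lower. Aldh1a2, the main retinoic acid synthesis enzyme of the embryo, was 5.01-fold lower and the retinol uptake receptor gene Stra6 3.75-fold, while Rbp4 was 2.66-fold higher. Wnt pathway genes had a median of −0.45, below all random lists, with 6 of 20 members at least 2-fold lower. They included the ligand gene Rspo3 (2.9-fold), the transcription factor gene Lef1 (2.71-fold) and the antagonist gene Dkk1 (2.55-fold), whereas the R-spondin receptor gene Lgr4 was 2.63-fold higher. The BMP and TGF-beta list did not stand apart, at percentile 33.63, with 16 of 22 members within 2-fold. Its other members went both ways, with Inhba (9.69-fold), Tgfb2 (4.27-fold) and Bmp6 (3-fold) higher and Bmp3 2.88-fold lower. The hedgehog list, at percentile 65.36, likewise held Hhip at 5.26-fold higher and Foxf2 at 5.51-fold lower, and the Notch list, at percentile 70.07, held Dll1 at 3.5-fold and Hes1 at 2.12-fold higher. Hypoxia and glycolysis genes had a median of 0.55, above all random lists, with Bnip3 2.79-fold and Aldoa 1.97-fold higher, although 20 of 21 members differed by less than 2-fold. The 25 cell cycle genes differed by less than 2-fold, at percentile 95.36.

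Markers of other cell types also differed between these libraries. Muscle genes had a median of 1.22, above all random lists, and 11 of 14 measured members were at least 2-fold higher in the Lgr5+ library, among them Tnnc1 (6.41-fold), Tnnt1 (4.34-fold), Des (3.96-fold) and Myod1 (3.63-fold). Epidermal genes had a median of 1.4, above all random lists, with Krtdap (8.42-fold), Krt5 (6.08-fold) and Krt14 (5.04-fold) among 9 of 14 members at least 2-fold higher, whereas Epcam (3.9 against 8.76 FPKM) and Krt18 (4.93 against 9.41 FPKM) were lower by less than 2-fold. Macrophage genes had a median of 0.46 at percentile 99.85, led by C1qa at 4.25-fold higher, but 8 of 12 members lay within 2-fold and Lyz2 was lower (7.48 against 13.7 FPKM). In the Lgr5+ library Tnnt1 stood at 30 FPKM, Krt5 at 12.6 FPKM and C1qb at 32.5 FPKM. Red blood cell genes went the other way. All 10 measured members were at least 2-fold lower in the Lgr5+ library, with a median of −4.24, below all random lists. Hba-a1 stood at 66.6 against 2043 FPKM, Hbb-b1 at 35.4 against 1207 FPKM and Alas2, the erythroid haem synthesis enzyme, at 1.16 against 25.4 FPKM. The largest fold of this comparison, 227 for Hba-a2, is uncertain because Hba-a1 and Hba-a2 are near-identical copies whose reads cannot be told apart, and the folds of Beta-s (40.4), Hbb-b1 (33.2) and Hbb-b2 (29) carry the same doubt. Hbb-y, an embryonic beta-like globin, was 5.66-fold lower, S100a8, a neutrophil protein gene, 6.72-fold lower, and the pseudogene Atp6v0c-ps2, which shares sequence with Atp6v0c, 28.3-fold lower. Endothelial genes had a median of −0.47 at percentile 0.13, with none of 10 members 2-fold different. Schwann cell and melanocyte genes did not stand apart, at percentile 19.42.

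Among lists that report on library quality, ribosomal protein genes were lower in the Lgr5+ library by a small margin, with a median of −0.25 below all random lists and none of 74 members 2-fold different. The histone list (percentile 30.55), the dissociation stress list (percentile 18.16) and the Y-linked list (percentile 20.25) did not stand apart. Fewer than 3 hindlimb or forelimb members were measured, and Pitx1 (56.5 against 83.2 FPKM), Tbx4 (22 against 28 FPKM) and Tbx5 (20.9 against 11.9 FPKM) differed by less than 2-fold. The macrophage call ended when only genes at 10 FPKM or more were used, at percentile 93.17, and the endothelial call ended with the mean in place of the median. The articular list stood apart with 4 other settings, such as the mean over members, and the histone list stood apart below the random lists at the 10 FPKM minimum.

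The comparison of Lgr5+ cells at E14.5 with Sox9+ cells at E13.5 set cells labelled as interzone against earlier digit cells sorted by the Sox9 reporter. By list medians, interzone, articular, tendon, muscle and macrophage genes were among those higher in the Lgr5+ library. Cartilage, chondrocyte maturation, hindlimb and dissociation stress genes were among those lower. Of 12492 genes measured, 541 were at least 2-fold higher in the Lgr5+ library and 495 at least 2-fold lower. Cilp led again at 49.2-fold, followed by Kera (34.9-fold), Adck3 (18.3-fold), Btc (13.8-fold), Dcn (13-fold), Gdf5, Glis1 (10.1-fold), the tendon gene Tnmd (9.73-fold), Barx2 (9.43-fold) and the cadherin gene Cdh13 (9.31-fold). The 10 lowest included the heat shock genes Hspa1a (52.7-fold) and Hspa1b (51-fold), the sphingomyelinase gene Smpd3 (26.6-fold), Comp (24.6-fold), Epyc (22.6-fold), Hspb1 (15.3-fold), the channel gene Panx3 (13.4-fold), Hoxc10 (13.2-fold) and Matn1 (12.9-fold). Hba-a2 was also among them, at 22.6-fold, while its copy Hba-a1 was 2.82-fold higher, and both are uncertain for the reason given above. The copies Hspa1a and Hspa1b are also near-identical, so how their reads were split is uncertain, but both were lower.

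Of 20 interzone genes, 8 were at least 2-fold higher in the Lgr5+ library and none 2-fold lower, with a median of 0.92 above all random lists. Gdf5, Osr1 (5.59-fold), the lysophospholipase gene Enpp2 (5.08-fold) and Dkk3 (4.46-fold) led. Tendon genes had a median of 1.73, above all random lists, with 10 of 16 members at least 2-fold higher. The articular list had a median of 0.52 at percentile 99.78, with Cilp, Col22a1, Thbs4 (4.5-fold) and Dpt (2.98-fold) among 5 of 14 members at least 2-fold higher. Tnc was the 1 member at least 2-fold lower, at 39.4 against 82 FPKM. Prg4, a member of both the interzone and articular lists, was low and also lower, at 1.19 against 2.36 FPKM. Cartilage genes had a median of −1.05, below all random lists, and 13 of 23 members were at least 2-fold lower. Matn1 stood at 546 FPKM in the Sox9+ library and 41.5 FPKM in the Lgr5+ library, and Lect1, which encodes chondromodulin, at 537 and 80.2 FPKM. Col2a1, the main cartilage collagen, stood at 5304 FPKM in the Sox9+ library, 2253 FPKM in the Lgr5+ library and 1401 FPKM in the Lgr5− library. Maturation genes had a median of −2.04, below all random lists, with 10 of 14 members at least 2-fold lower, including Smpd3, Panx3, Sp7 (8.06-fold) and the phosphatase gene Alpl (7.89-fold). Pthlh was again the 1 member at least 2-fold higher, at 50.1 against 21.3 FPKM.

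Hindlimb genes had a median of −2.45, below all random lists, with 4 of 5 measured members at least 2-fold lower in the Lgr5+ library. They were Hoxc10, Isl1 (7.71-fold), Hoxc9 (5.46-fold) and Pitx1 (2.82-fold), whereas the forelimb gene Tbx5 was 3.71-fold higher. The labels give forelimb as the source of both Lgr5 libraries and do not name the limb of the Sox9+ library. Limb patterning genes had a median of −0.14 at percentile 2.48, barely apart, with Shox2 5.91-fold and Meis1 4-fold lower and Tfap2b 3.05-fold higher. That call ended under 7 of the alternative settings, in 1 of which, with genes at 10 FPKM or more, the median turned positive, at 0.26. Perichondrium and bone genes did not stand apart, at percentile 63.7, with Dlx5 5.66-fold lower and Postn 2.28-fold higher.

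Dissociation stress genes had a median of −0.76, below all random lists, with 9 of 21 members at least 2-fold lower in the Lgr5+ library. Besides Hspa1a and Hspa1b these included Cyr61 (4.89-fold) and Hsp90aa1 (3.96-fold). Socs3 was the 1 member at least 2-fold higher, at 138.9 against 46 FPKM. Cell cycle genes had a median of −0.58, below all random lists, led by Mki67 (1.94-fold lower) and Ccna2 (1.89-fold lower), although each of the 25 members differed by less than 2-fold. BMP and TGF-beta genes had a median of −0.48, below all random lists, with the ligand gene Bmp2 3.62-fold lower but Inhba 3.66-fold, the antagonist gene Chrd 3.34-fold and Tgfb2 3.26-fold higher. Wnt genes (percentile 95.26), hedgehog genes (61.44), Notch genes (26.94), retinoic acid genes (39.42) and hypoxia genes (85.06) did not stand apart. Single members of these lists still differed by more than 2-fold, with the Wnt antagonist gene Frzb 6.99-fold lower, Dkk2 3.31-fold higher, Hhip 7.86-fold higher, Gli2 2.8-fold higher, Hey1 2.99-fold lower and Aldh1a2 6.18-fold lower.

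Muscle genes had a median of 1.17, above all random lists, with Myod1 6.69-fold and Tnnt1 5.99-fold higher among 10 of 15 members at least 2-fold higher in the Lgr5+ library. Macrophage genes had a median of 1.96, above all random lists, with C1qb 8.94-fold and Tyrobp 5.34-fold higher among 9 of 12. Epidermal genes had a median of 0.64, above all random lists, but split into Krtdap (6.19-fold) and Krt1 (3.67-fold) higher and Krt18 (4.7-fold) and Krt8 (3.57-fold) lower. Schwann and melanocyte genes had a median of −0.5 at percentile 1.56, although Ngfr was 2.83-fold higher. Endothelial genes (percentile 90.33), red blood cell genes (78.5) and Y-linked genes (45.73) did not stand apart by their medians, and for red blood cell genes the median of 0.22 and the mean of −0.39 differed in sign. Ribosomal protein genes had a median of −0.3, below all random lists, and histone genes a median of −0.26 at percentile 0.01, with Hist1h4i 3.94-fold and Hist1h2ab 3.54-fold lower. Stage, mouse line and sorting gate all differed between these libraries and cannot be told apart, and rescaling each library to TPM (values that sum to the same total) changed the split from 541 higher and 495 lower to 981 higher and 533 lower. The split was 487 and 528 with median of ratios, 489 and 525 with upper quartile, 483 and 521 with quantile normalization and 609 and 442 with the sum without the most abundant genes, so which side held more genes depended on the scaling. The epidermal call ended with the 10 FPKM minimum (percentile 57) and with the mean (percentile 96.47), the Schwann call ended with pseudocount 5 (percentile 3.02), and the Wnt list stood apart as higher under 4 settings. The hedgehog list did so with the 10 FPKM minimum (percentile 99.99) and the mean (percentile 97.73), and the perichondrium list with that minimum (percentile 98.7).

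The comparison of Lgr5− cells with Sox9+ cells set the GFP-negative digit cells at E14.5 against the earlier Sox9+ cells. Nearly every cartilage gene was lower in the Lgr5− library. By list medians, maturation, cell cycle, glycolysis and stress genes were also lower, and blood cell, limb patterning, Wnt and retinoic acid genes were higher. In several of these lists, most members lay within 2-fold. Of 12482 genes measured, 384 were at least 2-fold higher in the Lgr5− library and 617 at least 2-fold lower. Cartilage genes had a median of −1.93, below all random lists, and 21 of 22 measured members were at least 2-fold lower. Epyc was 30.6-fold lower, the gene of the cartilage proteoglycan Snorc (listed as 3110079O15Rik) 9.11-fold, Lect1 8.35-fold and Comp 7.21-fold. Maturation genes had a median of −1, below all random lists, with Smpd3 24.5-fold, Panx3 13.3-fold and Spp1 4.49-fold lower. Ibsp, a bone matrix gene, stood at 3 FPKM in the Sox9+ library and was listed at 0 in both Lgr5 libraries. Runx2 (10.7 against 12 FPKM) and Runx3 (10.9 against 12.5 FPKM) differed little between the Lgr5− and Sox9+ libraries.

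Interzone genes did not stand apart here, at percentile 83.71, and articular genes did not either, at percentile 88.53. Osr1 was 3.51-fold and Tgfbr2 2.26-fold higher in the Lgr5− library, while the BMP antagonist gene Chrdl1 was 2.98-fold and Barx1 2.27-fold lower. Tendon genes did not stand apart by their median of 0.1 (percentile 85.12), although 5 of 15 members were at least 2-fold higher, led by Kera (6.63-fold) and Dcn (4.12-fold), and the mean over members put the list above the random lists at percentile 99.94. Perichondrium and bone genes had a median of 0.31 at percentile 99.98, with 16 of 18 members within 2-fold and Foxc1 2.35-fold lower, and this call ended with the mean, at percentile 96.32. Limb patterning genes had a median of 0.71, above all random lists, with 8 of 24 members at least 2-fold higher, such as Tfap2b (4.56-fold), and 6 at least 2-fold lower, such as Shox2 (5.24-fold), Meis1 (4.17-fold) and Grem1 (3.87-fold). Hindlimb genes had a median of −2.79, below all random lists, with Hoxc10 14.9-fold, Hoxc9 6.91-fold and Isl1 6.9-fold lower, and Tbx5 was 2.18-fold higher.

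Wnt pathway genes had a median of 0.72, above all random lists, although 12 of 19 members lay within 2-fold. Dkk2 was 7.92-fold, Nkd2 5.06-fold and Axin2 3.19-fold higher, the last of these a widely used Wnt target gene. Frzb (7.88-fold) was 1 of 2 members at least 2-fold lower. Retinoic acid genes had a median of 0.84, above all random lists, with Stra6 3.45-fold and Rdh10 3.43-fold higher among 6 of 13 members. Hedgehog genes had a median of 0.51 at percentile 99.93, although 9 of 11 members lay within 2-fold, with Foxf2 6.02-fold higher and Foxf1a 5.3-fold lower. BMP and TGF-beta genes had a median of −0.49, below all random lists, with Bmp6 3.23-fold, Bmp2 3.22-fold and the BMP target gene Id4 2.68-fold lower. Notch genes did not stand apart, at percentile 45.39, with Hey1 3.2-fold lower. Cell cycle genes had a median of −0.81, below all random lists, with 7 of 25 members at least 2-fold lower, such as Cdc6 (2.25-fold) and Kif11 (2.21-fold). Hypoxia and glycolysis genes had a median of −0.72, below all random lists, with P4ha1 2.61-fold and Ero1l 2.37-fold lower, although 15 of 21 members lay within 2-fold. Dissociation stress genes had a median of −0.76, below all random lists, although 13 of 21 members lay within 2-fold. Hspa1a (65.2-fold), Hspa1b (64.7-fold) and Atf3 (4.53-fold) were among 7 at least 2-fold lower, and Socs3 was 2.95-fold higher. Hspb1 was 22.5-fold lower, the chemokine gene Cxcl1 13.9-fold, the growth factor gene Ctgf 12.6-fold and the secreted C1q family gene C1qtnf3 12.1-fold.

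Red blood cell genes had a median of 3.58, above all random lists, with 9 of 10 members at least 2-fold higher in the Lgr5− library, and 5 of them were among the 10 highest genes of this comparison (Hba-a1 85.1, Beta-s 57.6, Hbb-b1 50.8, Hbb-b2 35.6, Alas2 14.2). Macrophage genes had a median of 1.59, above all random lists, with Lyz2 7.07-fold higher, and endothelial genes a median of 0.76 at percentile 99.99, with Plvap 2.11-fold higher. S100a8 was listed at 0 in the Sox9+ library and stood at 11.5 FPKM in the Lgr5− library. The others among the 10 highest were the pseudogene Atp6v0c-ps2 (28.6-fold, uncertain as above), Chodl (15.1-fold), the hormone gene Sst (a log2 ratio of 3.75) and the agouti gene (listed as a, 11-fold). Epidermal genes had a median of −1.1, below all random lists, with Perp 4.96-fold and Krt14 3.53-fold lower, and Schwann and melanocyte genes a median of −1.35, below all random lists, with Sox10 2.94-fold lower. Muscle genes did not stand apart, at percentile 80.48, nor did Y-linked genes (92.11) or ribosomal protein genes (96.56). Histone genes had a median of −0.5, below all random lists, with Hist1h4i 3.83-fold lower. Stage, mouse line and gate again differed together, and the hindlimb call ended with the 10 FPKM minimum (percentile 2.78). The split of 384 higher and 617 lower became 706 and 644 when each library was rescaled to TPM, and 482 and 497 when it was rescaled to the sum without the most abundant genes. The excess of lower genes stayed with median of ratios (420 and 581), upper quartile (443 and 540) and quantile normalization (405 and 588), so both its size and its direction depended on the scaling.

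**Figure D2:**
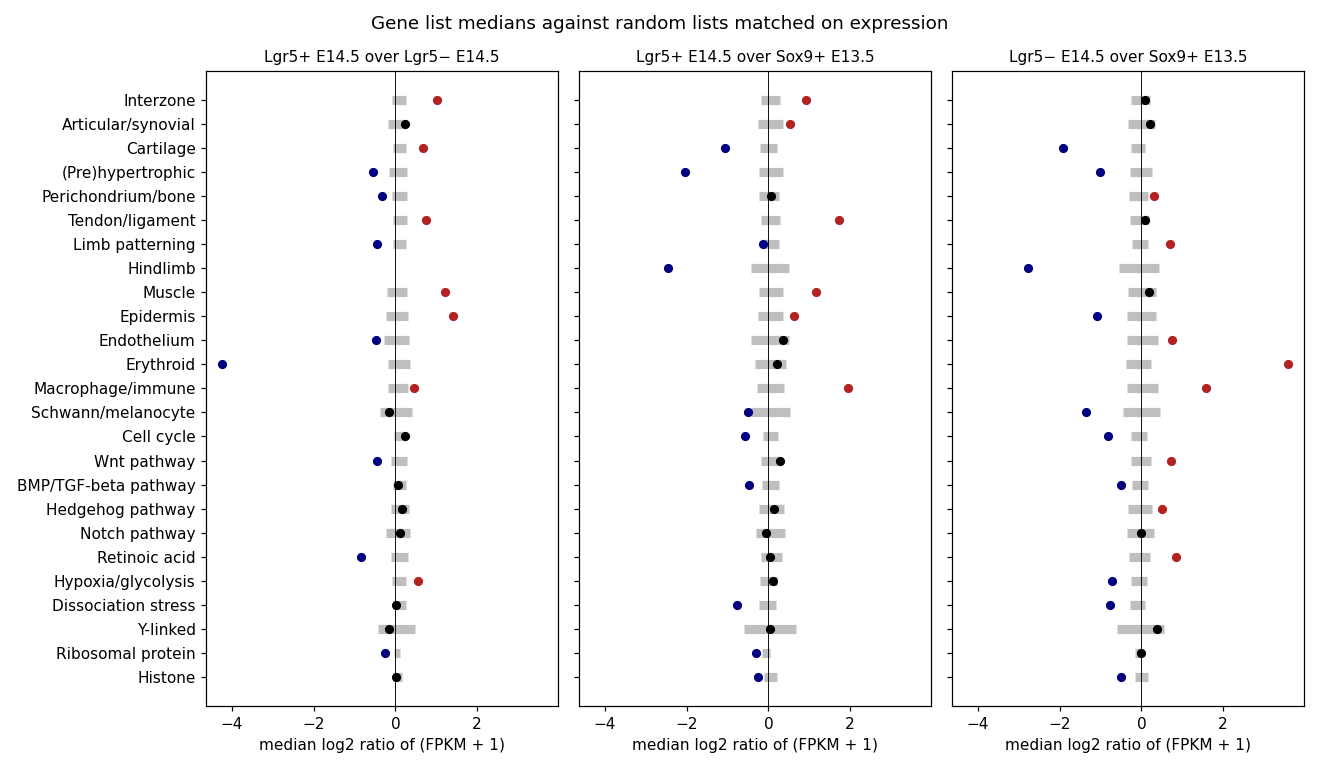
Median log2 ratio of FPKM + 1 of each gene list (rows) in the 3 pairs of libraries (panels), with red points above and blue points below the grey bars, the range of 10000 random lists matched on expression outside which a list stood apart, and black points inside them. Tendon genes stand at 0.74 and 1.73 in the pairs with the Lgr5+ library as numerator, and cartilage genes at 0.69 over the Lgr5− library but −1.05 over the Sox9+ library.

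Finally, genes were counted that set a single library apart from both others by at least 2-fold. The Lgr5+ library was highest for 241 genes, among them Gdf5, Cilp, Barx2, Btc, Glis1, Col22a1, Kera and Dcn, and lowest for 48, among them Aldh1a2, Runx2, Runx3 and Sp7. The Sox9+ library was highest for 310 genes, among them Matn1, Comp, Epyc, Panx3, Hspa1a and Hoxc10, and lowest for 125, among them Dkk2, Tfap2b and Tnmd. The Lgr5− library was highest for 121 genes, among them Hba-a1, Hbb-b1, Foxf2, Prrx2 and Stra6, and lowest for 112, among them Scrg1, Sox6 and Inhba. With TPM the Sox9+ library was highest for 314 genes and lowest for 282, and with the sum without the most abundant genes for 259 and 167, so this imbalance depended on the scaling, while the other scalings gave 300 to 314 and 124 to 131. Each of these counts uses the value of 1 library in both ratios, so chance variation of that library enters both. The 2 Lgr5 libraries shared day and mouse line, and the Sox9+ library differed from both in these. The design alone may therefore raise the Sox9+ counts, and the counts of the 3 libraries should not be ranked.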

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

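All alternatives reported here were planned, and none was added later. Counts are given in the order Lgr5+ over Lgr5− higher and lower, Lgr5+ over Sox9+ higher and lower, Lgr5− over Sox9+ higher and lower, then highest and lowest by 2-fold in the Sox9+, Lgr5+ and Lgr5− libraries. With pseudocount 0.1 these were 694, 458, 900, 785, 721, 958, 511, 371, 373, 177, 258 and 255. With pseudocount 5 they were 202, 81, 193, 193, 139, 273, 138, 36, 111, 21, 44 and 37. At 4-fold they were 95, 39, 93, 79, 62, 92, 49, 12, 48, 8, 26 and 14, fewer by construction. With a minimum of 10 FPKM, which tests fewer genes, they were 242, 115, 273, 257, 180, 369, 179, 67 and 136, then 64 highest in the Lgr5− library, and the other 2 stayed within 1.5 times. With TPM, 5 of 12 counts moved by over 1.5 times: 355 lower than Lgr5−, 981 higher than Sox9+, 706 higher in Lgr5− than Sox9+, 282 lowest in Sox9+ and 198 highest in Lgr5−. TPM raises every value and so weakens the pseudocount and the minimum, and it moved the median log2 ratio of all genes from 0.06 to 0.21 for Lgr5+ over Sox9+ and from −0.01 to 0.11 for Lgr5− over Sox9+. The sum without the most abundant genes moved the latter to 0.1, and median of ratios and upper quartile moved that of Lgr5+ over Lgr5− from 0.08 to −0.01 and −0.04. No filter, median of ratios, upper quartile, quantile normalization and the sum without the most abundant genes left all 12 counts within 1.5 times. Of the list medians under all alternatives, 774 kept their call, 14 came to stand apart, 13 no longer did and 1 reversed. For Lgr5+ over Lgr5−, the articular list came to stand apart with no filter (0.365), the 10 FPKM minimum (1.092), TPM (0.408) and the mean (0.832), and the histone list with the 10 FPKM minimum (−0.114), while the macrophage list no longer did with that minimum (0.471), nor the endothelial list with the mean (−0.304). For Lgr5+ over Sox9+, limb patterning no longer stood apart with pseudocount 5 (−0.091), no filter (−0.139), median of ratios (−0.188), upper quartile (−0.185), the mean (−0.157) or unmatched random lists (−0.139), and its median reversed to 0.26 with the 10 FPKM minimum. In the same pair the Wnt list came to stand apart with pseudocount 0.1 (0.362), no filter (0.265), the 10 FPKM minimum (0.911) and TPM (0.504), the hedgehog list with that minimum (0.799) and the mean (0.456), perichondrium with that minimum (0.28) and red blood cells with the mean (−0.386). Epidermis no longer stood apart with that minimum (0.213) or the mean (0.364), nor the Schwann list with pseudocount 5 (−0.184). For Lgr5− over Sox9+, the hindlimb list no longer stood apart with the 10 FPKM minimum (−0.944), nor perichondrium with the mean (0.171), while tendon came to with the mean (0.618). The cause of these list changes was not tested. Mean and median also differed in sign for the Schwann list (Lgr5+ over Lgr5−) and for perichondrium and hypoxia (Lgr5+ over Sox9+), none of which stood apart by either. No log2 ratio of a named gene with a 2-fold difference changed sign, and sign changes of smaller ratios were not counted. Of the 348 log2 ratios of named genes, of any size, 87 moved by over 1.5-fold with pseudocount 0.1, 144 with pseudocount 5 and 18 with TPM. Depth is unknown, so the floor of low values could not be set.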

Other observations

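The gene lists used in this part were written after the patterns they bear on had been seen but before their own values were looked up, except that Hspa8, Cpa3 and Cma1 had been seen, and the tests of hindlimb tissue and of a lower share of the main cell type, and those of lists without a minimum or without genes already seen, were chosen only after their results were seen. Several mast cell genes were highest in the Lgr5− library. Cpa3, a mast cell carboxypeptidase, stood at 15.6 FPKM in the Lgr5− library, 2.79 FPKM in the Lgr5+ library and 0.81 FPKM in the Sox9+ library, the chymase gene Cma1 at 12.4, 2.26 and 0.39 FPKM, and the histamine synthesis gene Hdc at 7.31, 0.71 and 0.85 FPKM. Without Cpa3 and Cma1, which had been seen, 4 members of the list were measured between the Lgr5 libraries, with a median log2 ratio of −0.65 for Lgr5+ over Lgr5− (percentile 0.46). The same set had a median of 1.27 for Lgr5− over Sox9+ (4 measured, percentile 99.94) and did not stand apart for Lgr5+ over Sox9+ (3 measured, percentile 47.22). The gene Gata2, which other cells also express, went the other way, at 12.6 FPKM in the Sox9+ library against 7.85 FPKM in the Lgr5− library.

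The 10 genes of the endoplasmic reticulum stress list were also ordered across libraries. Their median log2 ratio was 0.45 for Lgr5+ over Lgr5− (percentile 99.82), −0.57 for Lgr5+ over Sox9+ (percentile 0.01) and −1.01 for Lgr5− over Sox9+ (below all random lists). Between the Lgr5 libraries all 10 differed by less than 2-fold. Herpud1 stood at 99.3 FPKM in the Sox9+ library, 40.2 FPKM in the Lgr5+ library and 21.1 FPKM in the Lgr5− library, and Ddit3 at 31, 14.7 and 11.3 FPKM. The 15 further heat shock genes did not stand apart between the Lgr5 libraries (percentile 89.76).

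Some heat shock genes were far higher in the Sox9+ library, where Hspa1a was 52.7-fold higher than in the Lgr5+ library and 65.2-fold higher than in the Lgr5− library. Scaling is argued against, since the median log2 ratio of all genes was only 0.06 for Lgr5+ and −0.01 for Lgr5− over Sox9+. A rescaling by median of ratios could therefore move Hspa1a only a little, and the smaller of its log2 ratios was still 5.78. A heat shock response of those cells is a candidate explanation, because 15 further heat shock genes lay at percentile 99.98 or above over each Lgr5 library, although their medians were modest (−0.45 for Lgr5+ and −0.73 for Lgr5− over Sox9+), 9 of 15 lay within 2-fold in each pair, Hsph1 (6.59-fold and 7.2-fold higher) was the extreme, and Cryab was higher in the Lgr5+ library (4.79 against 1.23 FPKM). Without Hspa8, which had been seen, 14 genes were left. Their median was −0.415 for Lgr5+ over Sox9+ (percentile 0.07) and −0.707 for Lgr5− over Sox9+ (below all random lists). Whether a broader protein folding stress was part of this pattern cannot be told. The endoplasmic reticulum stress list lay at percentile 99.99 or above over each Lgr5 library, which met the prediction written in advance. Only 3 and 5 of its 10 members were at least 2-fold higher over the Lgr5+ and Lgr5− libraries. That list also stood apart for Lgr5+ over Lgr5− (percentile 99.82), where the 15 further heat shock genes did not (percentile 89.76). It therefore does not follow the heat shock pattern alone. Whether a heat shock response arose in the embryo or in handling, and whether stage, mouse line or gate account for the pattern, stays open and was not tested.

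Shox2, Hoxa11, Meis1 and Hoxc genes were higher in the Sox9+ library, while the distal genes Hoxd13 and Hoxa13 were lower, at log2 ratios of −1.08 and −1.22 against the Lgr5+ library. More proximal limb tissue in that sample stays open: the 9 measured of 10 further proximal genes stood apart as higher in the Sox9+ than in the Lgr5+ library (percentile 0.57 for Lgr5+ over Sox9+), but lay at percentile 13.78 for Sox9+ over Lgr5−, which misses the bound set in advance yet lies inside the random range. By the prediction written in advance, missing the bound in either pair counted against this explanation. With all 10 members, the median for Lgr5− over Sox9+ turned from 0.19 to −0.15, at percentile 15.55. That again misses the bound but lies inside the random range. The explanation is left open because the members were split. The 5 Hox members, led by Hoxa10 at 80 FPKM against 34.2 and 48.7 FPKM, were higher in the Sox9+ library. Irx3 and Irx5 were lower in it than in the Lgr5− library. The list was also higher in the Lgr5− library than in the Lgr5+ library (median −0.37 for Lgr5+ over Lgr5−, percentile 0.13). Hindlimb tissue in the sample is a candidate explanation that cannot be told apart from stage, line and gate, because the labels do not name its limb. The forelimb gene Tbx5 was lower in it by log2 ratios of −1.89 and −1.12, and the hindlimb genes Hoxc10, Hoxc9 and Isl1 stood below 1 FPKM in the forelimb-labelled libraries. Other hindlimb genes were present there too, with Tbx4 at 22 and 28 FPKM and Pitx1 at 56.5 and 83.2 FPKM. In the Sox9+ library Tbx4 was only 1.64-fold and 1.3-fold higher, and Pitx1 2.82-fold and 1.92-fold higher.

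Muscle, epidermal and some macrophage genes were higher in the Lgr5+ than in the Lgr5− library, with 8 of 12 macrophage genes within 2-fold. A lower share of the main cell type could raise every other type alike. Such a uniform rise is argued against by the red blood cell median log2 ratio of −4.24 in the same pair. That value was already known when the test was chosen. It does not bear on a lower share that raised muscle, epidermal and macrophage cells but not red blood cells, which stays open. Muscle cells in the GFP+ gate may contribute, since the 7 measured of 17 further muscle genes lay at percentile 100, and, as the 1 FPKM minimum favours large folds in such low genes, all 17 were also used without it, with 15 higher and a median of 0.74, again at percentile 100 (100 over Sox9+ and 59.62 for Lgr5− over Sox9+). Epidermal cells may contribute as well, with 9 measured of 19 further genes at percentile 99.96 (99.7 without the minimum), although only 2 were 2-fold higher, the list did not stand apart over Sox9+ (percentile 39.94), Epcam and Krt18 of the first list went the other way, and the most abundant, Lor, stood at 32.2 FPKM in the Sox9+ library against 21.8 and 10.1 FPKM. The gate should remove cells without the Lgr5 reporter, 11 of 19 muscle and 8 of 19 epidermal genes of the first lists reached 1 FPKM in the Lgr5− library as well, and expression of these genes in Lgr5+ cells themselves stays open and was not tested.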
